A study of Gallus gallus with 14 samples.

How the data were processed

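The data are 14 small RNA libraries of chicken spleen, 5 tumorous, 4 control and 5 survivor, grouped by the sample group in the labels. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with the NEBNext small RNA kit. The deposited values are raw counts of reads per mature chicken miRNA, in 1 table for the whole series, and were not normalized. The submitters' processing notes name BWA and featureCounts 0.18.1, without saying which step each served. The genome build, the miRNA annotation and the treatment of reads that match several miRNAs are not given in the sources used here. Members of near-identical families (let-7, miR-34b and miR-34c, miR-15 and miR-16, miR-30, miR-146) could therefore share reads, and their split is uncertain. Whole numbers with different totals per library were checked in the table. No column of per-sample values lacked a sample (0 columns). Each library's column was matched to its sample by the sample's own label. PCR reads without molecular identifiers are not independent molecules, so the floor of 3 counts covers counting error only.

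Of 1205 miRNAs, 428 were at 0 in every library. The remaining 777 were filtered with filterByExpr (minimum count 10, minimum total 15), which kept 302. Libraries were scaled by TMM, with factors of 0.815 to 0.950 in the tumorous group and 0.882 to 1.29 in the others. The main test was edgeR's quasi-likelihood F-test (glmQLFit, glmQLFTest) on the counts, in 1 fit of all 14 libraries with a factor of 3 groups and no covariate. Benjamini-Hochberg adjustment ran over all miRNAs tested within each of the 3 comparisons, with a threshold of 0.05. Adjusted p-values without another name come from this test. CPM values are per effective library size, and log2 CPM used a prior count of 2. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

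Before the data were examined, the groups, main design, most alternatives and 20 lists of miRNAs (families, clusters and cell type markers) were fixed. 17 lists had at least 3 tested members. Each was tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 51 list tests, and beside it with an estimated correlation and with fry. With the estimated correlation 0 of the 7 calls held. Counts of members past the threshold are adjusted over all miRNAs tested, and those adjusted over the list alone are given where they differ. The list of viral miRNAs was not analysed here, and single-member lists (miR-223, miR-2954) were read as miRNAs. The lists overlap: miR-155 stands among oncomiRs and lymphocyte miRNAs and miR-130a is in 2 lists. The rule for named miRNAs, fixed at the same time, took in each comparison the 8 higher and 8 lower past the threshold with the largest change and a mean of at least 50 CPM, and up to 4 of the most abundant members per list. Members outside this rule (miR-146a-5p, miR-146c-3p, miR-21-3p, miR-221-5p, miR-181b-5p, miR-130b-5p, miR-130a-5p, let-7d, miR-145-3p, miR-10a-3p, miR-29b-2-5p, miR-29c-5p, miR-30c-2-3p, miR-30a-3p, miR-16-1-3p, miR-16-2-3p, miR-103-3p, miR-26a-2-5p, miR-107-3p, miR-129-1-3p, miR-375, miR-200a-5p, miR-449d-5p, miR-17-3p, miR-217-5p, miR-216b and, against controls, miR-214 and miR-126-5p) are named to complete a count or, for miR-17-3p, miR-217-5p and miR-216b, singled out, and were chosen after their values were seen.

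Simulated counts with 200 of 777 miRNAs changed were used to test the fit. For tumorous against control, 303 miRNAs were tested, and 44.7% of the 2-fold and 80.9% of the 4-fold changes were called, with 0 calls among 209 unchanged miRNAs. For tumorous against survivor the shares were 36.2% and 87.2%, with 1 call among 209. For survivor against control, simulated without change, 0 of 303 were called. In the simulated tumorous and control libraries camera also gave a smaller p for a list of raised miRNAs than for an unchanged list. Shared libraries between comparisons were weighed with 100 simulated draws and by splitting the shared group. Other splits of the libraries were refitted 100 times per comparison, in a fit of the 2 groups compared.

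Alternatives were RLE, upper-quartile and no scaling beyond library size, no filter, a mean of at least 50 CPM, a 2-fold minimum, DESeq2, limma-voom with quality weights, robust dispersion, only the 2 groups compared, sex as a covariate, birds labelled female (control 1 included), a replicate block, removal of the 10 most abundant miRNAs and of each library in turn. Added after seeing the data were fits without control 1, control 2 and survivor 5, with control 1 counted as male, without tumorous 1 and 2, without survivor 1 and control 3, and with day as a numeric covariate in the tumorous and control libraries, whose days overlap. Day was not fitted for the survivors, since day 55 held only survivors. miRNAs were matched by name to chromosomes of assembly GRCg7b only for the sex check and to name miRNAs on chromosomes Z and W, because the build behind the counts is not known here.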

Results

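Small RNA was sequenced from 14 chicken spleens in an experiment on Marek's disease, in which an avian herpesvirus causes T-cell lymphomas. Birds given 2000 plaque-forming units of the GA strain of the virus gave 5 spleens with tumours, labelled tumorous, and 5 spleens labelled survivor. Birds given 0.2 mL of diluent gave 4 control spleens. The tumorous spleens were taken on days 31 to 42, the controls on days 37 to 43 and the survivors on day 55. The labels leave open whether these days count from hatching or from inoculation. The total count per library ranged from 6132708 in tumorous 3 to 10686682 in control 2, and 3 counts corresponded to 0.252 to 0.568 CPM (counts normalised to library size). Of 1205 chicken miRNAs, 777 had a count in at least 1 library and 302 were tested. The 10 most abundant miRNAs took 77.8% to 85.8% of each library's counts. No pair of libraries was alike within sampling noise, since the smallest chi-square per degree of freedom was 310 over all pairs and 457 within a group. The median SD of log2 CPM was 0.48 in the tumorous group, 0.35 in the controls and 0.36 in the survivors. The first principal component held 39.4% of the variance and ran from -18.0 to -3.47 in the tumorous libraries, with survivor 1 at -0.196 and every other library at 3.37 or above. Control 1 (9.49), control 2 (9.28) and survivor 5 (10.5), described below for sex, had the highest scores, so this component did not follow the tumorous outcome alone.

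The labelled sex of the birds was read from miR-2954, a Z-linked miRNA that is higher in male birds. It stood at 5634 CPM in control 2 and 6095 CPM in survivor 5, the libraries labelled male. Control 1, labelled female, had 5985 CPM, while every other library labelled female had 444 to 957 CPM. miR-7b, which lies on chromosome W of assembly GRCg7b, stood at 1.54 CPM in control 1, 1.06 in control 2 and 1.20 in survivor 5, against 1712 to 10475 CPM in every other library. All 5 tumorous birds were labelled female, so sex was not balanced between the groups.

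**Figure D1:**
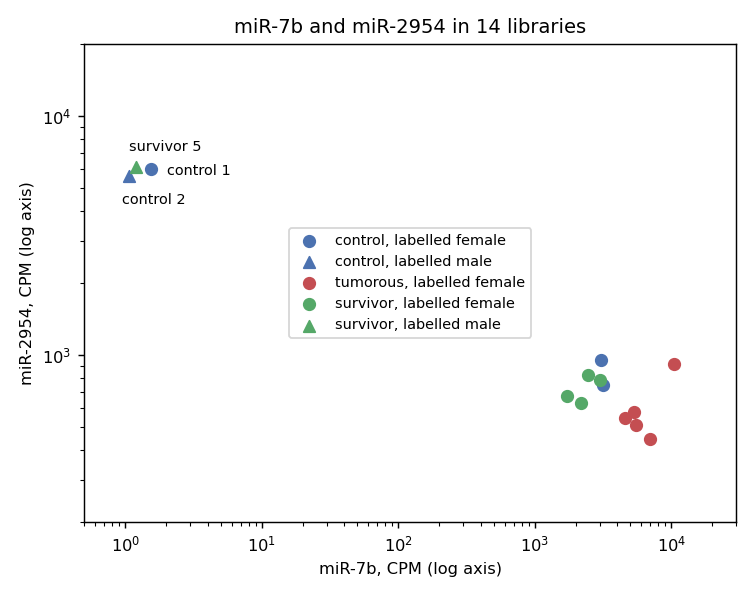
CPM of miR-7b (x, log axis) against CPM of miR-2954 (y, log axis), 1 point per library, coloured by group and shaped by labelled sex. Control 1, labelled female, lies beside both libraries labelled male.

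The tumorous and control spleens were compared to ask which miRNAs accompany the tumours. miR-146c, of a family induced by NF-kB signalling, was 9.76-fold higher in the tumorous spleens (log2 fold change 3.29, SE 0.42, adjusted p = 0.000418), at 194640 ± 89197 CPM (SD, n = 5) against 19946 ± 2684 CPM (n = 4). miR-21-5p, an oncogenic miRNA of many tumours, rose 2.70-fold (log2 fold change 1.44, SE 0.24, adjusted p = 0.00133), from 128445 ± 13955 to 347434 ± 87856 CPM. miR-147, which Toll-like receptor signalling induces in macrophages, rose 5.47-fold (log2 fold change 2.45, SE 0.32, adjusted p = 0.000418), and miR-7 rose 3.84-fold (log2 fold change 1.94, SE 0.38, adjusted p = 0.00309). Both arms of miR-1388a fell: miR-1388a-3p was 6.12-fold lower (log2 fold change -2.61, SE 0.51, adjusted p = 0.00312), at 539 ± 342 against 3297 ± 844 CPM, and miR-1388a-5p was 5.23-fold lower.

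miR-458a-3p fell 4.47-fold (adjusted p = 0.00499) and miR-460a-5p fell 3.22-fold (adjusted p = 0.00281). let-7k-5p, of the tumour-suppressive let-7 family, fell 2.35-fold to 2085 ± 510 from 4907 ± 117 CPM (adjusted p = 0.00133). miR-454-3p fell 2.30-fold (adjusted p = 0.00145), miR-27b-3p fell 2.01-fold (adjusted p = 0.0041) and miR-30b-5p fell 1.96-fold (adjusted p = 0.00166). For each miRNA given so far in this comparison, all 5 tumorous libraries lay beyond all 4 controls. miR-148a-3p, an abundant miRNA, fell 1.90-fold from 280667 ± 52309 to 147420 ± 54211 CPM (adjusted p = 0.00856), with 4 of 5 tumorous libraries below every control. The change of miR-27b-3p was no longer past the threshold without control 1, control 2 and survivor 5, an alternative chosen after seeing the data (log2 fold change -0.60, from -1.01, adjusted p = 0.103). miR-27b-3p lies on chromosome Z of assembly GRCg7b, so its fall against controls may in part follow the sex of the birds. How large that part is remains uncertain, since the alternative left only control 3 and control 4 as controls. With day as a covariate in a fit of the tumorous and control libraries only, also chosen after seeing the data, 3 of the miRNAs above had folds near those given but wider errors, and were no longer past the threshold. They were miR-458a-3p (log2 fold change -1.97, SE 0.68, from -2.16, SE 0.47, adjusted p = 0.0963), miR-27b-3p (-0.99, SE 0.29, from -1.01, SE 0.21, adjusted p = 0.0576) and miR-148a-3p (-0.92, SE 0.36, from -0.93, SE 0.23, adjusted p = 0.121). That fit also leaves out the survivors, so a call lost in it, here or below, cannot be put down to day alone. The fall of miR-2954 (log2 fold change -2.47, SE 0.78, adjusted p = 0.029) may in part follow the sex of the birds. Without the 3 libraries described for sex it was -0.53 (adjusted p = 0.231). Those libraries were singled out by miR-2954 itself, among other values, so a smaller fall without them was fixed in advance and decides nothing. Leaving out 1 library ended the call of miR-2954 in 6 of 9 settings, up to adjusted p = 0.0913 without control 2.

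**Figure D2:**
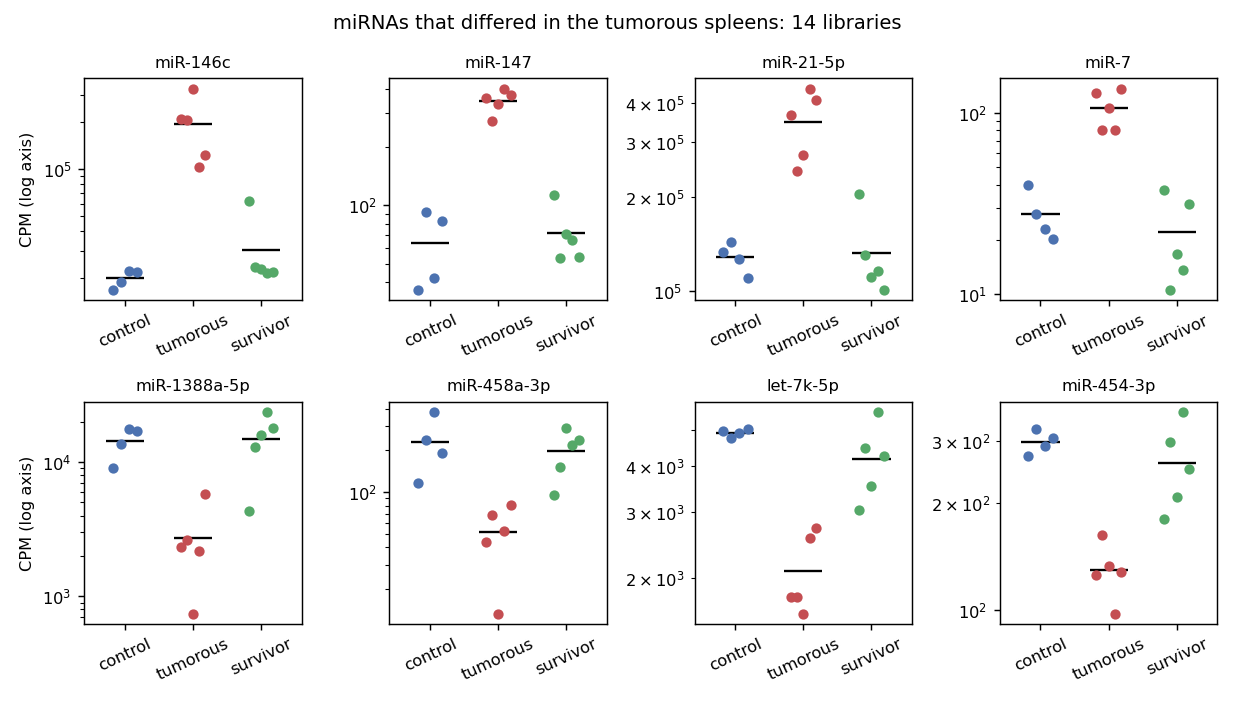
CPM (log axis) of 8 miRNAs in the control, tumorous and survivor libraries, 1 point per library, with a black line at each group's mean. For miR-146c, the tumorous libraries lie between 103896 and 329694 CPM and the controls between 16703 and 22308 CPM.

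In all, 95 of the 302 miRNAs passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 48 higher and 47 lower in the tumorous spleens. The change was at least 2-fold for 57 of them, 34 higher and 23 lower. The values of 68 of the 95 did not overlap between the groups. Over all miRNAs tested, 23.8% did not overlap, where chance gives 1.59%. With libraries scaled by their size alone, 112 passed, 33 higher and 79 lower, so that 29.5% of the calls were higher against 50.5%. That scaling placed the median of all miRNAs at -0.23, against 0.04 with TMM (log2). Without control 1, control 2 and survivor 5, chosen after seeing the data, 34 miRNAs passed, all among the 95. Only control 3 and control 4 were left as controls there. Control 3 differed from the other controls in some miRNAs, described below. With labelled sex as a covariate and all libraries kept, 73 passed, all among the 95. With control 1 counted as male in that fit, also chosen after seeing the data, 68 passed, 64 of them among the 95. With day as a covariate 37 of 283 passed, 36 of them among the 95, against 62 in the same fit of the tumorous and control libraries without day. Without control 1, control 2 and survivor 5, 1 of 13 lymphocyte miRNAs, 2 of 6 oncomiRs and 2 of 17 members of the 17-92 cluster and its paralogue rose and 1 fell. Of the lists with falls, 2 of 12 let-7 miRNAs, 3 of 11 of the miR-130/miR-301 family and 0 of 5 of the miR-23/miR-24/miR-27 clusters fell there, and 0 of 15 endothelial and stromal, 0 of 8 epithelial and 0 of 8 miRNAs of the miR-34 and miR-449 family passed in edgeR.

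Of 13 lymphocyte miRNAs, 5 rose, 0 fell and 8 did not pass (camera adjusted p = 0.0403, but adjusted p = 0.498 with an estimated correlation). They were miR-146c, its other arm miR-146c-3p, miR-146a-5p, miR-142-3p and miR-146b-5p, which rose 3.06-fold (adjusted p = 0.00546). Of 6 lymphoma-linked oncomiRs, 4 rose, which were both arms of miR-21, miR-222 and miR-221-5p (camera adjusted p = 0.0409, but adjusted p = 0.59 with an estimated correlation). miR-155, the oncomiR of which Marek's disease virus carries a functional relative, was at 3596 ± 1208 CPM in the tumorous spleens and 3555 ± 1570 CPM in the controls (log2 fold change 0.02, SE 0.30, adjusted p = 0.963). In the 17-92 cluster and its paralogue, 6 of 17 tested members rose and 1 fell, miR-92-3p (camera adjusted p = 0.0653). The most abundant members, miR-363-3p, miR-20b-5p and miR-17-5p, did not pass (adjusted p = 0.171, 0.212 and 0.104). Of 11 members of the miR-130/miR-301 family, 4 fell and 0 rose (camera adjusted p = 0.0483, but adjusted p = 0.59 with an estimated correlation). These were miR-454-3p, miR-301b-5p (2.08-fold), miR-130c-3p (1.60-fold) and miR-130b-5p. At a mean of at least 50 CPM, 3 members of this family were left and it did not pass (camera adjusted p = 0.172). Scaled by library size alone, 4 lymphocyte miRNAs and 2 oncomiRs rose, 4 members of the 17-92 cluster and its paralogue rose and 2 fell, and 7 members of the miR-130/miR-301 family fell.

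Of 12 let-7 miRNAs, 4 fell and 0 rose, namely let-7k-5p, let-7j-3p, let-7i and let-7d. The median of this list was 0.02 and its mean -0.13, and the median took either sign between scalings (camera adjusted p = 0.657). In the miR-23/miR-24/miR-27 clusters miR-27b-3p and miR-23b-3p fell among 5 tested members, or 3 when adjusted over the list alone (camera adjusted p = 0.165). All 5 lie on chromosome Z of assembly GRCg7b. Without control 1, control 2 and survivor 5, chosen after seeing the data, 0 of 5 fell against control 3 and control 4, the only controls left. There miR-23b-3p was at -0.33 (SE 0.24, from -0.56, adjusted p = 0.396). Against survivors 2 of 5 still fell in that setting, so how far these falls follow sex is uncertain. Of 14 endothelial and stromal miRNAs, 4 fell and 0 rose (camera adjusted p = 0.122): miR-145-5p, a smooth muscle miRNA, fell 1.64-fold (adjusted p = 0.0108), as did miR-214, miR-126-5p and miR-10a-3p. The abundant miR-143-3p, at 141454 ± 41604 against 197718 ± 56477 CPM, did not pass (adjusted p = 0.157). Of 3 erythroid miRNAs, miR-144-3p rose 5.31-fold (adjusted p = 0.0239), while miR-451 had adjusted p = 0.488 (camera adjusted p = 0.56). The myeloid miRNA miR-223 was at 902 ± 454 against 958 ± 164 CPM (adjusted p = 0.826).

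In the 29 and 30 families, 3 of 12 rose (miR-30e-5p, miR-29b-2-5p and miR-29c-5p) and 2 fell (miR-30b-5p and miR-30c-2-3p). In the 15/16 family, 1 of 9 rose, miR-16-1-3p, and 1 fell, miR-15c-5p. Of 17 miRNAs studied earlier in Marek's disease, 3 rose (miR-140-5p, miR-26a-2-5p and miR-29b-2-5p) and 2 fell (let-7i and miR-107-3p), or 1 and 0 when adjusted over the list alone. Of 9 neural miRNAs, miR-7 rose and miR-129-1-3p fell, or 1 and 0 when adjusted over the list alone. Among 4 liver miRNAs miR-148a-3p fell, and 0 of 3 muscle and 0 of 6 miRNAs of the miR-99/miR-100/miR-125b clusters passed in edgeR. Scaled by library size alone, 2 rose and 6 fell in the 29 and 30 families, 1 and 4 in the 15/16 family, 1 and 3 among the miRNAs studied earlier, 1 and 2 among neural miRNAs and 0 and 1 among muscle miRNAs, so falls outnumbered rises there. The camera adjusted p of these 7 lists was 0.657 or above. Several of these calls lay near the threshold and were lost without 1 library. The highest adjusted p was 0.171 for let-7i without tumorous 1 (log2 fold change -0.34, from -0.41). Without control 1 it was 0.103 for miR-23b-3p (-0.46, from -0.56), 0.0834 for miR-222 (0.46, from 0.55), 0.076 for miR-142-3p (0.84 in both) and 0.0545 for miR-144-3p (2.41 in both). Without control 3 it was 0.0945 for miR-140-5p (0.35, from 0.47) and 0.0689 for miR-15c-5p (-0.40, from -0.65), and without tumorous 4 it was 0.0662 for miR-30e-5p (0.55, from 0.62). With day as a covariate and the survivors left out, chosen after seeing the data, the calls of miR-144-3p (1.88, SE 0.97, from 2.41, adjusted p = 0.225), miR-146b-5p (1.74, SE 0.51, from 1.61, adjusted p = 0.0574) and miR-23b-3p (-0.55, SE 0.24, from -0.56, adjusted p = 0.152) were lost, among others.

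The largest fold changes belonged to miRNAs of ciliated and other epithelia, and they lay mostly in a pair of tumorous libraries. miR-34c-5p and miR-34b-5p, miRNAs of multiciliated cells, rose with log2 fold changes of 8.63 (SE 2.06, adjusted p = 0.00731) and 8.54 (SE 2.16, adjusted p = 0.00926). miR-34b-5p was at 2074 CPM in tumorous 2 and 108 CPM in tumorous 1, at 5.87, 1.82 and 1.41 CPM in tumorous 3, 4 and 5, and at 3.01 CPM or less in every other library. The epithelial miRNA miR-200a-3p was at 2401 and 224 CPM in tumorous 2 and 1, at 116, 14.0 and 11.6 CPM in tumorous 3, 4 and 5, and at 50.9 CPM or less elsewhere. Of 5 tested members of the miR-34 and miR-449 family, 3 rose (the third was miR-449d-5p) and miR-34a-5p fell. Adjusted over the list alone, 4 rose and 1 fell (camera adjusted p = 0.657). Of 8 epithelial miRNAs, 5 rose (miR-200a-3p, miR-200a-5p, miR-200b-3p, miR-429-3p and miR-375) and miR-183 fell (camera adjusted p = 0.582). Without tumorous 2, the log2 fold change was 5.17 for miR-34c-5p, 4.65 for miR-34b-5p, 2.26 for miR-200b-3p (adjusted p = 0.0388) and 2.12 for miR-200a-3p (adjusted p = 0.0619). Without tumorous 1 and 2, chosen after seeing the data, miR-34c-5p was at 2.06 (adjusted p = 0.0174) and miR-429-3p at 2.97 (adjusted p = 0.0124), while miR-34b-5p was at 1.34 (adjusted p = 0.104), miR-200b-3p at 1.48 (adjusted p = 0.145) and miR-375 at 1.61 (adjusted p = 0.110, from 4.70). The call of miR-449d-5p (log2 fold change 4.15, adjusted p = 0.042) rested on tumorous 2, without which it was at 0.996 (adjusted p = 0.366), and without tumorous 1 and 2 it was at 0.02 (adjusted p = 0.991). With day as a covariate, miR-34c-5p was at 8.90 (SE 3.14) and miR-34b-5p at 8.61 (SE 3.26, adjusted p = 0.119), neither past the threshold. Without control 1, control 2 and survivor 5, also chosen after seeing the data, miR-34c-5p was at 8.60 (SE 3.22, adjusted p = 0.116) and miR-34b-5p at 8.77 (SE 3.42, adjusted p = 0.119). The calls of miR-183 and miR-34a-5p were lost on leaving out 1 library in 5 and 6 of 9 settings, with log2 fold changes of -1.25 without control 2 (from -1.39, adjusted p = 0.0762) and -0.63 without tumorous 3 (from -0.80). miR-217-5p and miR-216b, miRNAs of the pancreas chosen after their values were seen, were at 175 and 22.4 CPM in tumorous 1 and at 18.6 and 3.70 CPM or less in every other library, tumorous 2 included, and did not pass (adjusted p = 0.242 and 0.294).

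**Figure D3:**
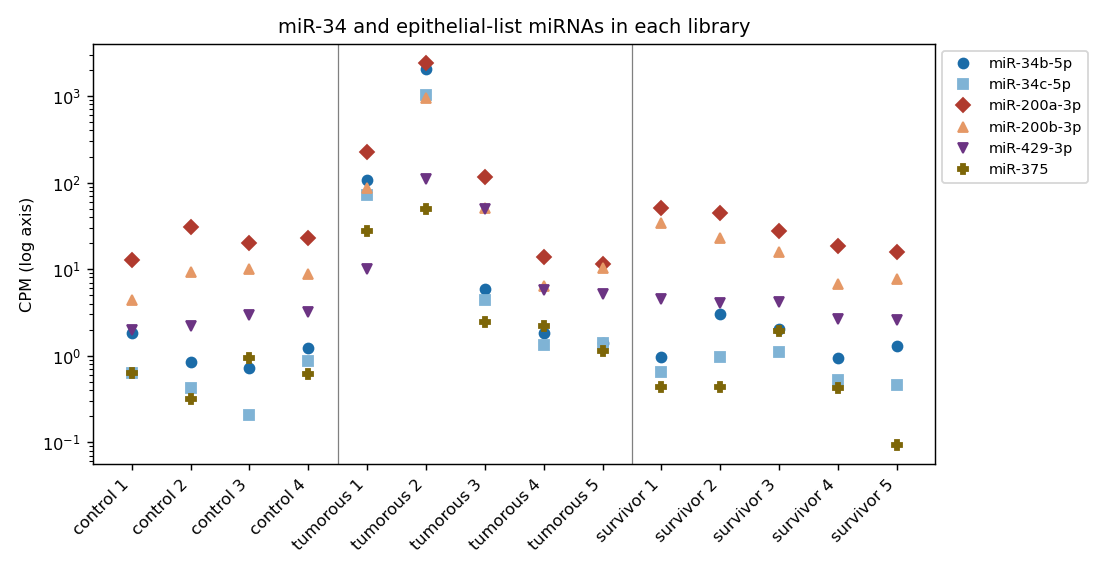
CPM (log axis) of 6 miRNAs of the miR-34 and miR-449 family and the epithelial list in each of the 14 libraries, 1 symbol per miRNA. The highest values are those of tumorous 2, with miR-200a-3p at 2401 CPM and miR-34b-5p at 2074 CPM.

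The tumorous and survivor spleens came from birds given the same virus dose, and the comparison asked how the outcomes differ. miR-146c was 6.40-fold higher in the tumorous spleens (log2 fold change 2.68, SE 0.37, adjusted p = 0.000714), with the survivors at 30402 ± 17919 CPM (n = 5). miR-147 was 4.87-fold higher (log2 fold change 2.28, SE 0.29, adjusted p = 0.000663), miR-7 was 4.84-fold higher (log2 fold change 2.28, SE 0.35, adjusted p = 0.00115) and miR-21-5p was 2.62-fold higher (log2 fold change 1.39, SE 0.22, adjusted p = 0.00115). miR-1388a-3p was 5.78-fold lower (log2 fold change -2.53, SE 0.50, adjusted p = 0.00335) and miR-1388a-5p was 5.45-fold lower. miR-30b-5p fell 2.19-fold (adjusted p = 0.000714), and miR-126-5p, an endothelial miRNA, fell 2.19-fold from 2400 ± 412 to 1098 ± 343 CPM (adjusted p = 0.00335). miR-214 fell 2.12-fold (adjusted p = 0.00305) and miR-145-5p 1.97-fold (adjusted p = 0.00259).

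Of the 302 miRNAs, 94 passed, 54 higher and 40 lower in the tumorous spleens, and 55 changed at least 2-fold, 36 up and 19 down. Scaled by library size alone, 120 passed, 28 higher and 92 lower, so that 23.3% were higher against 57.4%, with the median of all miRNAs at -0.38. In the 17-92 cluster and its paralogue, 10 of 17 members rose and 1 fell (camera adjusted p = 0.0217, but adjusted p = 0.59 with an estimated correlation). Scaled by library size alone, 4 rose and 4 fell (camera adjusted p = 0.0529). Its most abundant member, miR-363-3p, rose 1.63-fold (adjusted p = 0.00903). Of 6 oncomiRs, 4 rose (camera adjusted p = 0.0298, but adjusted p = 0.59 with an estimated correlation), and miR-222 rose 1.70-fold (adjusted p = 0.00473). Of 13 lymphocyte miRNAs, 5 rose (camera adjusted p = 0.0403, but adjusted p = 0.498 with an estimated correlation), with miR-181b-5p in place of miR-142-3p. Of 14 endothelial and stromal miRNAs, 5 fell and 0 rose (camera adjusted p = 0.0403, but adjusted p = 0.678 with an estimated correlation). They were miR-145-5p, miR-145-3p, miR-214, miR-126-5p and miR-10a-3p. In the miR-130/miR-301 family 4 of 11 fell and miR-130a-5p rose, or 6 and 1 when adjusted over the list alone (camera adjusted p = 0.165). Scaled by library size alone, 2 lymphocyte miRNAs and 2 oncomiRs rose, and 9 endothelial and stromal miRNAs and 7 of the miR-130/miR-301 family fell.

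In the miR-34 and miR-449 family 4 of 5 rose and miR-34a-5p fell, and of 8 epithelial miRNAs 5 rose and miR-183 fell. miR-34c-5p had a log2 fold change of 8.19 (adjusted p = 0.00473), miR-449d-5p one of 4.85 (adjusted p = 0.0164) and miR-449a one of 3.67 (adjusted p = 0.0314). Without tumorous 2, miR-34c-5p was at 4.73 (adjusted p = 0.00665), miR-449d-5p at 1.67 (adjusted p = 0.131), miR-449a at 0.27 (adjusted p = 0.739), miR-200a-3p at 1.55 (adjusted p = 0.131) and miR-200b-3p at 1.15 (adjusted p = 0.227). Without tumorous 1 and 2, miR-34c-5p was at 1.63 (adjusted p = 0.0323) and miR-34b-5p at 0.85 (adjusted p = 0.275, from 8.04). In the let-7 family 2 of 12 fell, let-7k-5p and let-7j-3p, in the miR-23/miR-24/miR-27 clusters 2 of 5 fell, miR-27b-3p and miR-23b-3p, and miR-144-3p rose among 3 erythroid miRNAs (log2 fold change 2.14, adjusted p = 0.025). The call of miR-144-3p was lost without 1 library in 4 of 10 settings, up to adjusted p = 0.0614 without survivor 4 (log2 fold change 1.998). Those of miR-183 and miR-30e-5p were lost likewise, up to adjusted p = 0.0778 without survivor 4 (-1.06, from -1.26) and 0.0906 without tumorous 4 (0.47, from 0.59). In the 29 and 30 families 2 of 12 rose (miR-30e-5p and miR-29c-5p) and 3 fell (miR-30b-5p, miR-30c-2-3p and miR-30a-3p), or 3 and 4 when adjusted over the list alone. In the 15/16 family miR-16-1-3p rose and miR-16-2-3p fell among 9, or 1 and 0 when adjusted over the list alone. Of 17 miRNAs studied earlier in Marek's disease 2 rose, miR-103-3p and miR-130a-5p, or 0 when adjusted over the list alone. Of 9 neural miRNAs 1 rose, miR-7, and 1 fell, miR-129-1-3p, or 1 and 0 when adjusted over the list alone. By edgeR, 0 of 4 liver, 0 of 3 muscle and 0 of 6 miRNAs of the miR-99/miR-100/miR-125b clusters passed, and the other lists had camera adjusted p of 0.286 or above. Scaled by library size alone, 0 rose and 6 fell in the 29 and 30 families, 1 and 5 in the 15/16 family, 0 and 5 among the miRNAs studied earlier, 0 and 4 in the let-7 family, and 0 erythroid miRNAs passed in edgeR. All survivors were taken on day 55 and no tumorous spleen after day 42, so day and outcome were not separable.

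Both comparisons of the tumorous spleens called largely the same miRNAs, of which 42 were higher in both and 36 lower in both, with 0 in opposite directions. Independent lists would share 8.58 and 6.23. The log2 fold changes correlated across miRNAs, which are not independent replicates, at r = 0.947. The comparisons share the tumorous libraries, and simulated unchanged groups gave r = 0.467 and 0 shared calls. Where no group changes hardly any miRNA is called, so that 0 does not show how much the shared libraries add to the overlap of calls. The covariance was 1.62 against 0.104 simulated, a difference of 1.52. With the tumorous libraries split between the comparisons, r averaged 0.642 and 8 to 26 calls were shared.

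**Figure D4:**
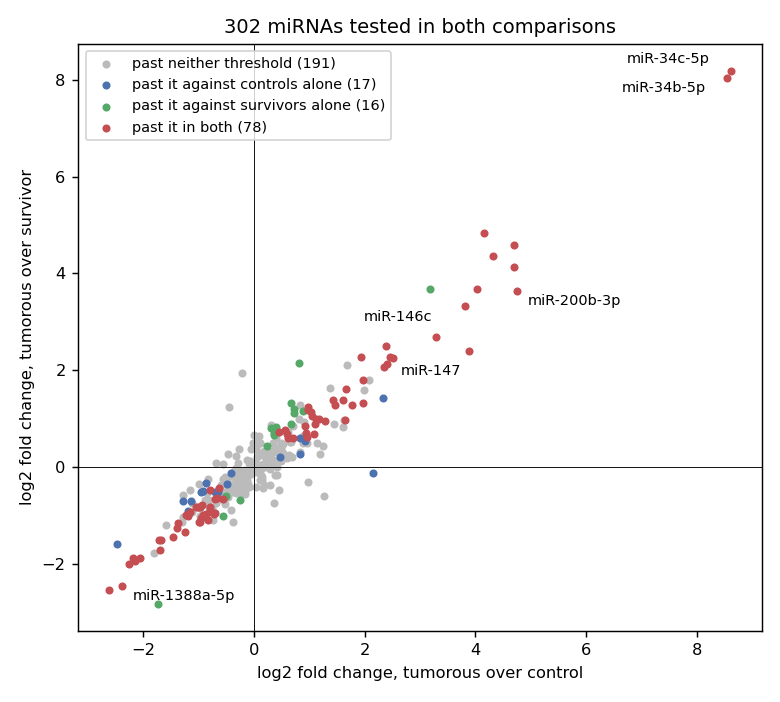
Log2 fold change of tumorous over control (x) and of tumorous over survivor (y), 1 point per tested miRNA, coloured by the comparisons in which it passed an adjusted p of 0.05. The 78 miRNAs past it in both lie in the same direction in both.

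The survivor and control spleens were compared to ask what infection without the tumorous outcome leaves in the spleen. All survivors were taken on day 55 and the controls on days 37 to 43, so day and infection were not separable in this comparison. The miRNAs that marked the tumorous spleens stood near the control level in the survivors: miR-21-5p was at 132411 ± 41612 CPM against 128445 ± 13955 (log2 fold change 0.04, SE 0.23), miR-147 at 71.6 ± 24.7 against 63.7 ± 28.5 CPM (0.17, SE 0.30) and miR-1388a-3p at 3118 ± 1473 against 3297 ± 844 CPM (-0.08, SE 0.50). miR-146c was at 30402 ± 17919 against 19946 ± 2684 CPM (0.61, SE 0.38), with 62431 CPM in survivor 1 and 21486 to 23363 CPM in the other survivors. miR-148a-3p was at 206816 ± 30367 against 280667 ± 52309 CPM (-0.44, SE 0.23). By edgeR, 0 of 302 miRNAs passed, the smallest adjusted p was 0.958, and 10 had an unadjusted p under 0.05, where chance gives 15.1. DESeq2 and limma-voom also called 0, with 24 of 767 and 21 of 302 at an unadjusted p under 0.05. In each of the 17 lists tested 0 members passed, and no list passed the camera test, with 0.122 the smallest adjusted p. Half-widths of the 95% confidence intervals had a median of 0.65 on the log2 scale. The fold changes of survivors and of tumorous spleens over the same controls correlated at r = 0.357, where simulated unchanged groups gave 0.557. With the controls split it averaged 0.186, and the covariance was 0.209 against 0.131 simulated, a difference of 0.0781.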

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

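All tests of the 3 patterns below were chosen only after the result was seen, while the counts of other splits were planned. Among 225 groups of 4 or 5 libraries, 16 had 1 library far from the rest by a gap test, where chance, at about 1 in 20 groups, gives 11.25.

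Control 1 and survivor 5 stood apart in miR-2954 and miR-7b. In survivor 5, labelled male, miR-2954 was at 6095 CPM (630 to 825 in the other survivors) and miR-7b at 1.20 CPM (1712 to 3016). Control 1, labelled female, had miR-7b at 1.54 CPM and 1.02 times the mean miR-2954 of the libraries labelled male, which is consistent with a male bird or its RNA under this label. Set against control 3 and control 4, the median of 7 other miRNAs on chromosome Z of assembly GRCg7b, less that of 151 autosomal miRNAs, was 0.47 (log2) in control 1 and 0.88 in control 2, while in the tumorous and survivor libraries labelled female, each set against the others of its group, it was -0.26 to 0.30, so that control 1 lay between and this decides nothing. Male RNA mixed into a female library is argued against, since miR-7b in control 1 was 0.0498% of the mean of control 3 and control 4.

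Survivor 1 had the highest miR-146c of the survivors, at 62431 CPM (21486 to 23363 in the others), and miR-34a-5p at 89.7 CPM (58.8 to 64.6). Each library was placed on a scale from survivors (0) to the tumorous mean (1), set without that library and without survivor 1: survivor 1 lay at 0.341 and the other survivors at a mean of 0.0572 (SD 0.111, highest 0.208), so that it may hold a part of the tumorous profile. An exchange of labels with a tumorous library is argued against, since it needs a partner among the survivors and the lowest tumorous library lay at 0.542, 4.36 SDs above the mean of the other survivors (0.480 with survivor 1 kept among the survivors). This is weak evidence: a first bound on the lowest position was missed at 0.480 and was replaced by the bound in SDs after the result was seen. RNA carried over from a tumorous library cannot be told apart: the share needed differed between miRNAs higher and lower in tumorous spleens by -0.158 for the closest source (tumorous 4, 95% interval -0.331 to 0.0249), and only the other 4 sources gave intervals without 0. These intervals come from resampling miRNAs, which are not independent, and leave out the spread between birds, so they exclude no source. A single wrong label, or an early or limited tumour in this bird, was not tested and stays open.

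Of 13 tested members of the miR-34 and miR-449 family and the epithelial list, 9 lay above all control and survivor libraries in at least 2 tumorous libraries, while miR-34a-5p (38.1 and 55.0 CPM in tumorous 1 and 2, control mean 62.9) and miR-183 (11.5 and 28.97, control mean 40.0) were lower, and all 13 were above the floor of 3 counts in the controls on average (0.536 to 62.9 CPM). A scaling error is argued against in tumorous 2, since the largest ratio between scaling factors was 1.58 while the members' median ratio to controls was 78.8 there. The median ratio in tumorous 1, 4.87, was also above 1.58, but the test was set for tumorous 2 alone. A state shared by all 5 tumorous spleens is argued against too, since all 5 lay above all 9 other libraries for 2 of 13 members, miR-429-3p and miR-34c-5p. Cells of 1 outside tissue cannot be told apart from epithelial miRNAs in the tumours: the excess of miR-200 relative to miR-34b differed 23.8-fold between tumorous 3 and tumorous 2 (95% counting interval 16.1 to 41.6) and 1.64-fold between tumorous 1 and tumorous 2 (1.51 to 1.79), but no tissue profile was measured and the intervals leave out the spread between birds. Whether tissue was taken with the spleen was not tested. The pancreas miRNA miR-217-5p, chosen after its values were seen, was at 175 CPM in tumorous 1 and 18.6 or less elsewhere, tumorous 2 included. It therefore did not follow miR-34b-5p, which was highest in tumorous 2 (2074 CPM), and decides nothing on this pattern.

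The other values were as follows, each with the range of the rest of its group. miR-200b-3p was 4.45 CPM in control 1 (8.85 to 10.1), miR-24-3p was 5.73 CPM in control 2 (3.18 to 3.33) and miR-142-5p was 670 CPM in control 3 (3274 to 4345). By counts, control 3 was also the lowest control in miR-142-3p (49458, others 121220 to 170680), miR-30e-5p (40823, others 64775 to 91366) and miR-140-5p (5662, others 8123 to 10934). The gap test did not flag these, they were picked after their values were seen, and the cause was not tested. In tumorous 4, miR-144-3p was 148 CPM (890 to 1632) and miR-144-5p 21.3 CPM (112 to 170). miR-10a-5p was 16011 CPM in tumorous 3 (30624 to 35220) and miR-128-1-5p 11.6 CPM in tumorous 2 (19.1 to 23.4). In survivor 3, miR-142-3p was 15612 CPM (12081 to 13007) and miR-142-5p 5035 CPM (3108 to 3549), and miR-215-5p was 164 CPM in survivor 5 (33.2 to 51.8). The total count was 6132708 in tumorous 3 (8420030 to 9510086) and 8195284 in survivor 2 (9216182 to 9612170).

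Chance alone was argued against, but not excluded, for both counts with tumorous spleens. Of 126 possible splits 100 were drawn in each comparison, so 1 of 100 is the smallest share the draws can give. In a fit of only the groups compared, the real split of tumorous and control libraries called 62 miRNAs and the highest of the other splits 39, so that 1 of the 100 splits, the real one, gave as many. That other split placed tumorous 5 with controls. For tumorous and survivor the real split called 83 and the highest other 4, again with 1 of 100 giving as many. For survivor and control the splits decide nothing: the real split called 0, so all 100 gave as many by construction, and the highest other called 2.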

How the results depend on the processing

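The count against controls, 95, was 57 with a 2-fold minimum, 50 of 107 tested at a mean of at least 50 CPM, 62 in a fit of only the 2 groups, 61 in birds labelled female, control 1 among them, and, in alternatives chosen after seeing the data, 34 without control 1, control 2 and survivor 5, 62 without tumorous 1 and tumorous 2 and 37 with day as a covariate in the tumorous and control libraries (62 in that fit without day). The count against survivors, 94, was 55 with a 2-fold minimum and 46 at a mean of at least 50 CPM. By construction the minima admit fewer miRNAs and the other settings use fewer libraries, and beyond that the cause was not tested. Leaving out each library in turn gave 66 (without control 2) to 95 against controls, 73 to 98 against survivors and 0 to 0 for survivor against control. The survivor and control count was 0 in every one of the 27 alternatives. Without survivor 1 and control 3, also chosen after seeing the data, 71 miRNAs passed against controls, 65 of them among the 95. In that fit 104 passed against survivors. DESeq2 called 101 and 100 in the tumorous comparisons, limma-voom 97 and 97. The replicate numbers are shared between groups but do not pair the birds: over 13 same-number pairs the correlation of deviations ran from -0.248 to 0.230, with 5 over 0.1. With the replicate block, 78, 78 and 0 miRNAs passed. Of 51 list tests 7 passed, against 0 with an estimated correlation and 0 with library size alone. With fry, which compares no list with other miRNAs, 12 passed. With RLE scaling 6 passed, and at a mean of at least 50 CPM, where lists had fewer members, 5 passed. The cause of these differences was not tested. The correlation of survivor and tumorous fold changes over controls moved from 0.357 to 0.186 with the controls split, which removes the shared libraries.

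Of 69 called results of named miRNAs, 32 stayed past the threshold in every setting, and 36 that were not called passed in at least 1. miR-146c, miR-147, miR-7, miR-21-5p, both arms of miR-1388a, miR-460a-5p, let-7k-5p, miR-454-3p, miR-30b-5p and miR-301b-5p stayed past it in both tumorous comparisons. Over all settings of named miRNAs, 271 lost and 68 gained a call, and 5271 did neither. Among called results the 1 reversal was miR-449a against survivors, at -0.61 without tumorous 1 and tumorous 2 (adjusted p = 0.394). Against controls, where it was not called, miR-449a was at -1.09 there and at -0.20 without tumorous 2, and the cause was not tested. Removing viral miRNAs and merging same-name entries gave no value, since viral miRNAs were not analysed here and no name was repeated. Depth limits miRNAs near 3 counts, such as miR-34c-5p in the controls, whose fold is imprecise.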

Other observations

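All tests in this part were chosen only after the results were seen. Several precursors changed the balance of their arms in the tumorous spleens, which no comparison of single miRNAs describes. For miR-144, the log2 ratio of the 3p over the 5p arm averaged 2.92 (SD 0.24, n = 5) in the tumorous libraries and 1.16 (SD 0.998) in the other 9, a difference of 1.76. Among those 9, control 3 lay at -1.40 and the rest at 0.866 to 1.75, so control 3 enlarged the difference and the SD. For miR-17 the ratio was -4.97 against -6.29, a difference of 1.32. Control 3 was again the lowest of the other 9, at -7.11 with the rest at -6.48 to -6.03, so it enlarged this difference too. miR-17-3p rose 1.12 on the log2 scale over controls while miR-17-5p did not pass (log2 fold change -0.27, adjusted p = 0.104). The balance moved toward the other arm for miR-146c (difference -1.49), miR-146a (-0.80) and miR-10a (-0.69). In all, 14 of 31 precursors with enough counts on both arms passed an adjusted p of 0.05 in a two-sided exact permutation test over 2002 splits, 7 toward 3p and 7 toward 5p. For miR-144, miR-17, miR-146c and miR-10a all 5 tumorous libraries lay beyond the other 9, and p was 0.0005, the smallest the permutations can give (adjusted p = 0.00221). Among those 9, control 3 was also farthest from the tumorous mean for the called miR-148a, miR-363, miR-126, miR-130b, miR-210a and miR-425. For the remaining called precursors, miR-146c, miR-146a and miR-10a among them, another library was farthest. The arm test was not repeated without control 3, so how much it adds to these differences was not tested. In simulated independent ratios, each moved by more than its SD, 10 of 10 moved and 0 of 21 unmoved ratios were called. The simulated move was larger than differences such as those of miR-146a and miR-10a, so it says nothing on moves of that size. The 14 precursors are consistent with a difference in arm balance between tumorous and other spleens, as a hypothesis. Whether cell mixture, arm stability or the counting of reads shared between family members gives it was not tested.

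miR-7b had the highest levels in the tumorous spleens, at 4564 to 10475 CPM, but did not pass with all libraries, with control 1, control 2 and survivor 5 near 0 (log2 fold change 2.08, adjusted p = 0.362 against controls). No test without those 3 libraries is given, since it would choose libraries by miR-7b itself. The test with all libraries cannot tell the tumorous outcome from sex, since miR-7b lies on chromosome W of assembly GRCg7b and sex was not balanced. miR-7, a miRNA of the same family, rose in every setting, and whether these miRNAs share reads was not tested.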
